A study of Arabidopsis thaliana with 4 samples.

How the data were processed

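RNA of 4 seed samples, 2 of Ler-0 wild type and 2 of wrky43-1, was extracted with a hot borate protocol and total RNA was labelled with biotin, per the labels' protocols. The values used are the deposited series table of 38408 probe sets on 4 arrays. Their scale is not stated, and it was read as log2 because the deposited values lie between 1.18 and 14.27. The normalization and the summary of probes into probe sets are not given in the sources used here. No scanner values and no detection calls were used here, so signal over background is unknown.

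Genes were named through the platform's annotation, which can be old, with symbols and gene lengths from the reference annotation TAIR10.1. Of the 38408 probe sets, 16722 had 1 gene, 759 had several and 20927 had none in the table used here; the genes of 16574 (99.1%) of those with 1 gene were matched to the reference. For 14800 of the matched probe sets the reference gives only a locus code, so most well-studied genes were not named. No name was taken from a probe set with several genes. Of all probe sets 7134 had values identical to those of another on all 4 arrays, of which 38 were named. By their numbers, 38 named probe sets lay among probe sets of another chromosome, judged by the 20 nearest named ones; 16 genes were represented by such a probe set. No control probe sets could be told by their IDs (0 found). Gene length is the span of the gene in the reference, introns included, and no coordinates are printed because the build of the array's design is not given in the sources used here.

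The array medians differed by at most 0.088, under the limit of 0.1 set before the data were examined, so values were used as deposited. The 2 groups were compared with limma 3.58.1 (lmFit and eBayes, without trend, robust or block) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all 38408 probe sets and a threshold of 0.05. The fit had 2 residual and 2.34 prior degrees of freedom, and the median SE of a difference was 0.15 on the log2 scale. The tests, the alternatives, 19 gene lists and the rule for named genes were set before the data were examined. By that rule WRKY43 was named, then in each direction the 10 genes with the largest difference among those past the threshold with no overlap of the groups, filled up to 10 with the largest differences at an unadjusted p under 0.01 and no overlap, and 3 members with the smallest p of each list. The members of 5 or fewer that passed adjusted over a list alone were named too, after their values had been seen. For each gene the probe set with the highest mean over all arrays was used.

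Gene lists with at least 3 measured members were tested with camera (preset correlation 0.01) over 16550 genes, with an estimated correlation and with fry beside it. A member counts as measured if a probe set was paired with it alone, so other members may be on the array without a name. Of the 19 lists 8 had enough members and 4 had none. After the names, and before any difference, had been seen, 21 further lists were written, so that 29 of 40 lists were tested and adjusted together.

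The limma and camera steps were tested on simulated data. In 20 simulated sets of 38408 probe sets with the means and the prior variance of wrky43-1 against wild type, 200 probe sets were changed by a log2 difference of 1, 2 or 4; limma called 0.149%, 54.1% and 90.6% of these sizes, and 120 of 764160 unchanged ones. In 20 simulated sets of 16550 genes without change camera called 0 lists, and it called the ribosomal protein list in 20 of 20 after a shift of 0.3. These simulations held no correlation between genes. The shares called depend on how many probe sets were changed and by how much, so they are not the power of the real comparison. There, AT1G36920 missed the threshold at a log2 difference of 4.21.

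Alternatives covered the replicate number as a block, quantile normalization, centring, filters on low probe sets, the variance prior, array weights, leaving out each array, other thresholds, the choice of probe set and other set tests. Where probe sets were left out, the variance prior was refitted on the rest. Some were chosen after seeing the data: only probe sets with 1 gene, identical probe sets counted once, these and the filters with the prior of all probe sets kept, the trend on gene length removed, and probe sets among another chromosome left out.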

Results

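Gene expression was measured in Arabidopsis thaliana seeds of the accession Ler-0 and of the mutant wrky43-1, which carries a lesion in the gene of the transcription factor WRKY43. Dry seeds, 10 mg per sample, were kept for 4 days in liquid 0.5 MS, a plant culture medium, with 2 µM abscisic acid, the hormone that holds back germination. Each genotype had 2 biological replicates, and each replicate was hybridised to its own array, so that 4 arrays with 38408 probe sets each were compared. Median values on the log2 scale were 4.34 on both wild-type arrays and 4.43 and 4.40 on the wrky43-1 arrays. Across probe sets, Pearson's r was 0.986 between the wild-type arrays, 0.987 between the wrky43-1 arrays and 0.978 to 0.981 between arrays of different genotype. Probe sets of an array are not independent replicates, and the number of arrays limits the precision of every difference. The title of the series links WRKY43 to the content of polyunsaturated fatty acids and to abiotic stress tolerance of seeds. The single comparison of the design asks which transcripts differ when WRKY43 is mutated. No probe set used here was paired with WRKY43 (AT2G46130), so the level of the mutated gene was not analysed here and the genotype labels could not be checked with it.

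In wrky43-1, 1 probe set rose, and no probe set fell, at an adjusted p under 0.05 in limma. The probe set that rose, 13356037, was not paired with a gene and read 13.05 ± 0.0014 (SD, n = 2) in wrky43-1 against 8.51 ± 0.065 (SD, n = 2) in wild type, a 23.3-fold difference (log2 difference 4.54, SE 0.12, limma adjusted p = 0.0433). Leaving out any one of the 4 arrays, wild type or wrky43-1, gave 0 calls in both directions, while the log2 difference of this probe set stayed between 4.49 and 4.59 with SEs of 0.15 to 0.17 and the smallest p of all probe sets. Those fits have 1 residual degree of freedom, so the lost call says little about stability. Among the 16722 probe sets paired with 1 gene, 0 passed in either direction, while 924 of them read higher and 1022 lower in wrky43-1 at an unadjusted p under 0.05, where 836.1 in all are expected by chance. Long genes, treated below, were among the lower ones. Over all probe sets, 3477 read higher and 2660 lower at that threshold, where chance gives 1920.4. The 7134 probe sets with values identical to those of another held 1256 of the higher and 399 of the lower ones. Each of these was counted, so repeated values swell the surplus of higher over lower probe sets. In 48.1% of probe sets both arrays of one genotype lay beyond both arrays of the other, against 33.3% by chance.

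The named genes with the largest positive differences were AT1G36920 and AT1G36922, which are neighbours on chromosome 1. AT1G36920 read 8.11 ± 0.14 (SD, n = 2) in wrky43-1 and 3.90 ± 0.065 (SD, n = 2) in wild type, with a log2 difference of 4.21 (SE 0.13). At an adjusted p of 0.0538 in limma it missed the threshold. AT1G36922 read 7.10 ± 0.060 against 3.53 ± 0.26 (SD, n = 2 each; limma adjusted p = 0.103). AT2G34655 read 7.86 against 4.83 and AT3G27473 read 6.15 against 3.40, differences of 3.03 and 2.75 on the log2 scale with SEs of 0.15 and 0.14. Smaller positive differences were those of AT1G68230 (1.68), AT1G40104 (1.52), AT1G53035 (1.46) and AT2G32650 (1.38). AT4G03410 (2.54) and AT2G24390 (2.17) also belong to the 10 largest, but the probe sets that gave these values lay, by their numbers, among probe sets of other chromosomes. A probe set for AT4G03410 that lay among those of its own chromosome read a log2 difference of -0.06, and of 2 such probe sets for AT2G24390 one read 0.21 and the other 2.09, with values identical to those of a probe set among another chromosome. The identity of these transcripts is uncertain.

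On the negative side, STZ (AT1G27730, also called ZAT10), a zinc-finger repressor induced by cold, drought and salt, read 4.89 ± 0.040 (SD, n = 2) in wrky43-1 and 6.72 ± 0.32 (SD, n = 2) in wild type. Its log2 difference of -1.83 (SE 0.19) had a limma adjusted p of 0.157 over all probe sets and of 0.000922 adjusted over the list alone, a list that held 2 measured genes. AT1G47540 (log2 difference -2.15, SE 0.13) and AT3G43340 (-1.97, SE 0.14) had the largest negative differences. PDF2.1, a plant defensin gene, read 3.88 against 5.46 in wild type, and UGT73B4, of the family that transfers sugars to small molecules, read 4.41 against 5.74. AT1G03890, of the cupin family to which seed storage globulins belong, read 5.50 ± 0.080 against 6.79 ± 0.065 (SD, n = 2 each), a log2 difference of -1.29. The remaining genes of the 10 were AT5G23110 (-1.48), AT1G68570 (-1.34), AT4G36080 (-1.27) and AT4G27280 (-1.21). AT5G23110 and AT4G36080 are long genes, of 17576 and 18261 bp in the reference, and AT1G68570 had another probe set with a smaller difference of -0.46. None of these 20 genes passed the adjusted threshold of the planned limma fit, so their values are given without a call. An intensity trend in the variance prior gave 74 probe sets higher and 30 lower in place of 1 and 0. Of the 20 genes, AT1G36920, AT1G36922, AT2G34655, AT3G27473, AT4G03410, AT1G68230, AT1G47540, AT3G43340 and AT4G36080 then passed. In all, 14 probe sets with 1 gene were then higher and 11 lower. Those higher included probe sets of Cpn60beta4 (1.78) and AT3G51140 (1.66 to 1.77). These are not among the 20 genes, for which only the probe set with the highest mean was ranked. Some of those for AT3G51140 lay among probe sets of another chromosome. With both the variance prior and the adjustment taken from the 16722 probe sets with 1 gene, a choice made after seeing the data, 12 were higher and 6 lower (1 and 0 with the prior of all probe sets kept).

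**Figure D1:**
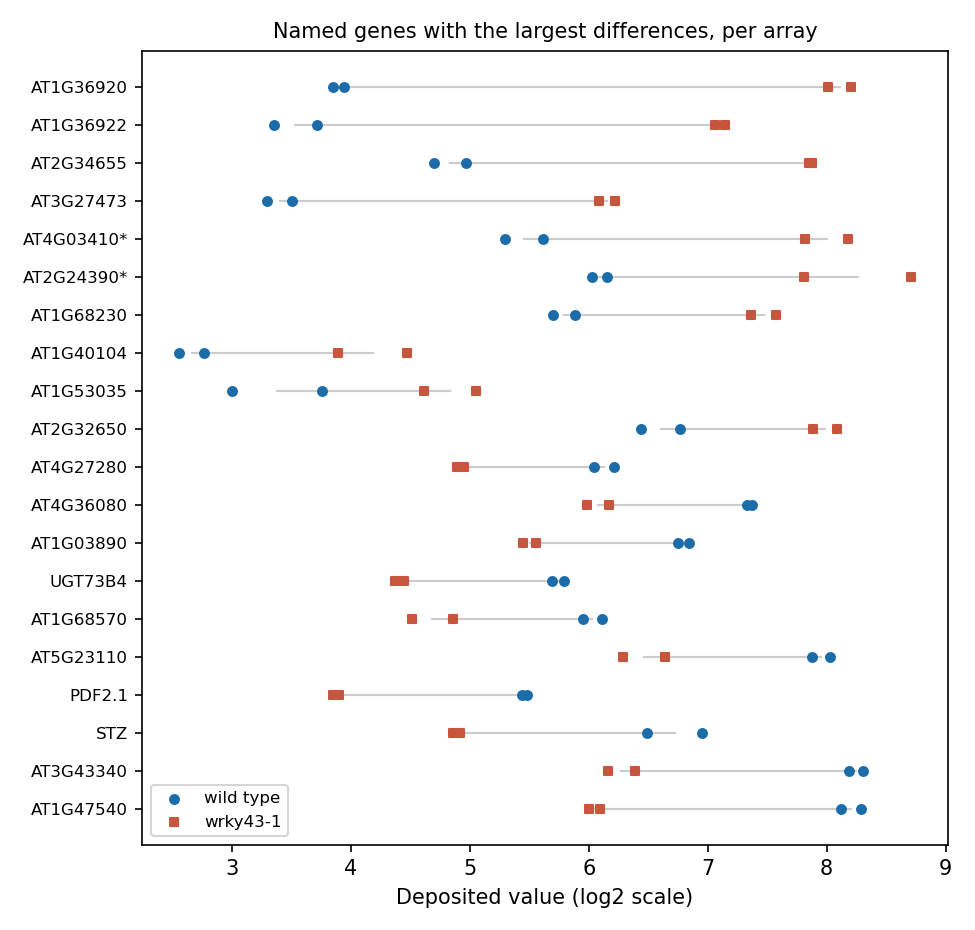
The horizontal axis gives the deposited value on the log2 scale and each row is a named gene, with circles for the 2 wild-type arrays and squares for the 2 wrky43-1 arrays; grey lines join the group means, and an asterisk marks genes whose probe set lay among those of another chromosome. In every row both arrays of one genotype lie beyond both arrays of the other, as the rule by which these genes were chosen required. The widest gap is that of AT1G36920, from 3.90 to 8.11.

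Genes of cytosolic ribosomal proteins, the protein part of the ribosomes that translate nuclear messages, rose as a group in wrky43-1. Of the 118 measured members 116 read higher, with a median log2 difference of 0.34 (camera adjusted p = 1.4e-27 with the preset correlation of 0.01). The adjusted p was 0.752 with an estimated correlation, at an unadjusted p of 0.0367, and 0.0667 in fry, so the call of the group was lost in both. Of its members 0 passed over all probe sets, 49 read higher and 0 lower at an unadjusted p under 0.05, and 5 passed when adjusted over the list alone. These 5 were AT3G53890 (log2 difference 1.08), AT2G39390 (0.96), AT1G07070 (0.93), AT1G26880 (0.92) and AT5G27850 (0.84), with SEs between 0.11 and 0.15. AT5G27850 read 9.92 ± 0.032 against 9.08 ± 0.0057 in wild type (SD, n = 2 each). It passed over all probe sets with an intensity trend in the variance prior.

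Ubiquitin-conjugating enzymes, which pass ubiquitin on to proteins that are to be degraded or altered, also rose as a group, with 14 of 15 measured members higher and a median log2 difference of 0.25 (camera adjusted p = 0.00387 with the preset correlation). The adjusted p was 0.752 with an estimated correlation and 0.146 in fry. UBC36 read 6.65 against 6.07 in wild type, UBC29 read 3.12 against 2.57 and UBC18 read 6.17 against 5.87. No member passed on its own, over all probe sets or adjusted over the list alone. The list was also no longer called without wild-type replicate 2 (adjusted p = 0.061) or without the lowest 50% of probe sets (0.0555; range over its alternatives 0.00184 to 0.752). Both called lists were written after the names of the probe sets had been read and before any difference had been computed.

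Differences between the genotypes went with gene length. Among the 123 named genes longer than 8000 bp the median log2 difference was -0.47 and 91.9% read lower in wrky43-1. Among the 1432 genes of 4000 to 8000 bp it was -0.18. At an unadjusted p under 0.01 in limma, 42 of the 123 and 73 of the 1432 were lower, and 0 were higher in either bin. Genes of 1000 to 2000 bp held 118 higher and 28 lower ones. All 16722 probe sets with 1 gene held 210 higher and 237 lower ones, so long genes supplied part of the lower side. Among the 5602 genes of 1000 to 2000 bp, the range in which the median length of the ribosomal protein genes (1565.5 bp) falls, the median was 0.03, and 0.13 for the 2275 of them with a level above the median gene. With the trend on gene length removed, an alternative chosen after seeing the data, both called lists passed again with the preset correlation. The camera adjusted p was 1.25e-26 for the ribosomal proteins and 0.00203 for the ubiquitin-conjugating enzymes. Without that removal both had an adjusted p of 0.752 with an estimated correlation. The removed trend was a straight line in log10 length, which moves genes near the median length of 1912 bp little. The median log2 difference went from 0.343 to 0.342 for the ribosomal proteins and from 0.251 to 0.274 for the ubiquitin-conjugating enzymes. That both lists passed again therefore says little about gene length. A list of further cupins and oleosins passed as lower with the trend removed (0.0252) but not in the planned test (0.05001). Its adjusted p was 0.752 with an estimated correlation and 0.146 in fry.

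**Figure D2:**
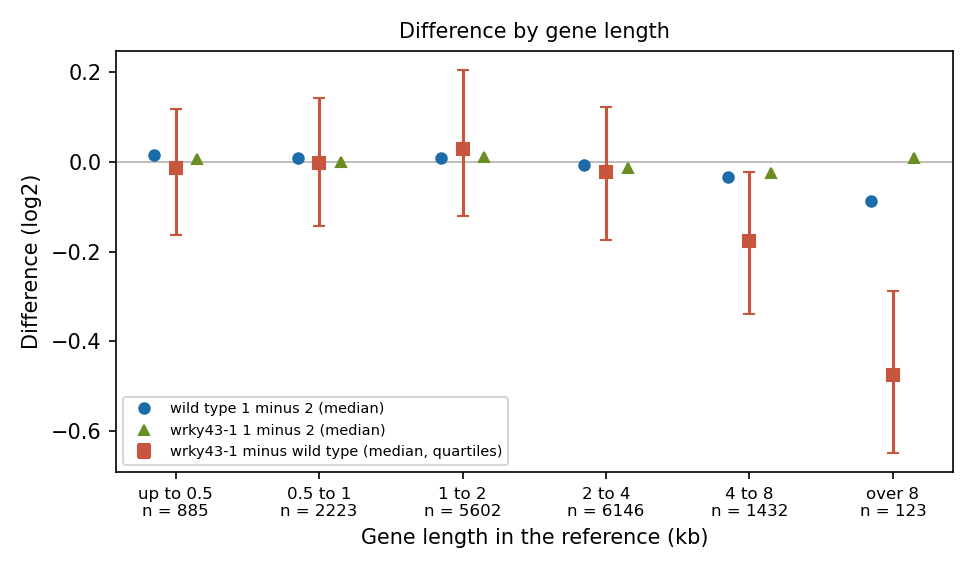
The horizontal axis gives gene length in the reference in bins, with the number of genes below each bin, and the vertical axis the difference on the log2 scale; squares with bars are the median and quartiles of wrky43-1 minus wild type over genes, circles the median of wild type 1 minus 2 and triangles that of wrky43-1 1 minus 2. The median of wrky43-1 minus wild type lies at -0.18 for genes of 4000 to 8000 bp and at -0.47 for longer ones.

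The lists fixed for lipids and seed reserves had few members with a name. No member of the list of fatty acid desaturation, elongation and triacylglycerol assembly had a named probe set. Nor did any of those for abscisic acid signalling, for abscisic acid synthesis and breakdown or for DNA replication and cell division. These genes may be on the array among the 20927 probe sets without a gene or the 759 with several, so their levels were not examined. Of plastid fatty acid synthesis 2 members were measured, the acyl-carrier thioesterases FATB (log2 difference -0.40, SE 0.15) and FaTA (-0.40, SE 0.20), and neither passed. The vicilin-like storage protein gene PAP85 read 12.67 in wrky43-1 and 12.86 in wild type, and the oleosin gene OLEO3 read 7.17 and 7.26. Of 2 seed maturation transcription factors measured, BZIP53 read 8.21 ± 0.11 against 7.68 ± 0.11 (SD, n = 2 each), a log2 difference of 0.53 that passed adjusted over the list alone (limma adjusted p = 0.0296) and not over all probe sets (0.224), while EEL read 8.82 against 8.88. Of 6 LEA and dehydrin genes, which protect drying seeds, 2 read higher and 4 lower (median log2 difference -0.05, camera adjusted p = 0.968), among them M17 (-0.50), LTI30 (0.33) and COR15A (0.15).

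Of the genes for cold, drought and salt response, STZ and KIN1 were measured, and KIN1 read 3.78 ± 0.36 against 3.37 ± 0.28 in wild type (SD, n = 2 each). The 4 heat shock genes had a median log2 difference of -0.05 (camera adjusted p = 0.968), with AT5G37670 at 0.64 and HSA32 at -0.47, and their mean of 0.02 had the other sign, which it lost with quantile normalization or centring. Of jasmonate and pathogen response, PDF1.2 (-0.08) and PDF1.2b (0.07) were measured, and PDF1.2b read -0.0027 with the arrays centred on the same median. Of flavonoid synthesis, DFR, which makes leucoanthocyanidins, read 5.50 against 4.99 (log2 difference 0.51, limma adjusted p = 0.0481 over the list alone and 0.249 over all probe sets). BAN read 2.79 against 2.65. All 4 measured gibberellin genes read higher, with a median log2 difference of 0.32 that missed the threshold (camera adjusted p = 0.0975), among them the receptor genes GID1A (0.32) and GID1B (0.33) and the F-box gene SLY1 (0.40). Without wild-type replicate 1 the gibberellin list was called (adjusted p = 0.011, the lowest of its alternatives). With all arrays its adjusted p was 0.752 with an estimated correlation, the highest of its alternatives, and 0.266 in fry. Of 7 WRKY family members 5 read lower, with a median of -0.36 (camera adjusted p = 0.13), among them WRKY47 (-0.49), WRKY20 (-0.40) and WRKY6 (-0.36).

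Lists of other tissues and stages that had enough members were not called. The root and root hair markers, with 2 measured, and DNA replication and cell division, with 0 measured, could not be tested. The 5 photosynthesis genes had a median log2 difference of -0.16 and a mean of 0.01 (camera adjusted p = 0.766), a mean that turned negative with quantile normalization or centring. Among them were LHCB4.1 at -0.35 and PRK at 0.67 (SE 0.48). PRK read 5.05 and 3.74 on the wrky43-1 arrays and 3.53 and 3.92 on the wild-type arrays, so its groups overlapped. All 3 genes of oil breakdown and the glyoxylate cycle read lower, ICL at -0.05, SDP1 at -0.11 and AIM1 at -0.17 (camera adjusted p = 0.764), and all 4 genes of cell wall loosening read lower, with a median of -0.14 (0.438). Endosperm and seed coat markers, 3 measured, had a median of 0.14 and a mean of 0.02 that turned negative with centring (camera adjusted p = 0.968), and the root hair genes EXPA7 and EXPA18 read -0.21 and 0.18 on the log2 scale.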

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

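Choices made only after the data had been seen are the 1-gene and identical-value settings, those with the prior of all probe sets kept, the removal of the length trend and the leaving out of probe sets among another chromosome. The probe sets higher in wrky43-1, 1 as reported, numbered 0 with the replicate block, 2 with the arrays centred on the same median, 6 without the lowest 50 percent, 74 with an intensity trend, 479 at an unadjusted p under 0.01 and a fold of at least 2, 12 among probe sets with 1 gene and 7 with identical probe sets counted once. Those lower, 0 as reported, numbered 30 with an intensity trend, 143 at an unadjusted p under 0.01 and a fold of at least 2, 6 among probe sets with 1 gene and 1 with identical probe sets counted once, and 0 in the others. Leaving out each array in turn gave 0 to 0 in both directions, with the lone array assumed to vary like the other group and 1 residual degree of freedom, which says little about stability: the called probe set kept a log2 difference of 4.49 to 4.59 (adjusted p 0.311 to 0.482). The filtered, 1-gene and counted-once settings change both the number of tests and the variance prior. With the prior of all probe sets kept, so that only the choice and number of tested probe sets changed, 2 were higher without the lowest 30 percent, 2 without the lowest 50 percent, 1 among probe sets with 1 gene and 2 with identical probe sets counted once, and 0 were lower in these settings. The 1 among probe sets with 1 gene is not the probe set called as reported, which was not paired with a gene. The prior degrees of freedom, 2.34 over all probe sets, were 4.01 over those with 1 gene. For the other settings the cause was not tested. The lists called, 2 as reported, numbered 1 without the lowest 50 percent, 0 with an estimated correlation and 1 to 3 without single arrays (1 without wild-type replicate 2); the ubiquitin-conjugating enzymes were lost without the lowest 50 percent. The further cupins and oleosins, not called as reported, were called lower with quantile normalization, an intensity trend, array weights, the mean of a gene's probe sets, the length trend removed, probe sets among another chromosome left out and without wrky43-1 replicate 2 (3 lists called in each of these settings). Their adjusted p was 0.752 with an estimated correlation and 0.146 in fry. The ribosomal proteins were called in each other setting run except the estimated correlation and fry (adjusted p 1.02e-36 to 0.752). Arrays with the same number share only a number (correlation of deviations -0.026), and the replicate block changed no other call.

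Of 1651 values of 115 named genes under alternatives, 1600 kept their side and direction, 42 newly passed, 0 were lost and 9 reversed. No named gene passed as reported, so a loss was not possible, and the 1600 passed in neither setting. Their number is therefore no measure of stability. Of 452 values for lists, 402 kept their side and direction, 10 newly passed, 6 were lost and 34 reversed. Settings with 1 value per gene changed both the number of tests and the prior: with 1 probe set per gene 6 genes were higher and 3 lower, and 1 and 0 with the prior of all probe sets kept. The reversals were of values that did not pass in either setting, and their cause was not tested. With quantile normalization the means were -0.036 for photosynthesis, -0.00660 for heat shock, -0.021 for beta-glucosidases and -0.025 for chloroplast-encoded genes. With centring they were -0.062, -0.057, -0.073 and -0.065 for these lists, -0.053 for endosperm and seed coat, -0.0040 for further photosystem genes, -0.030 for SWEET, -0.042 for RALF-like peptides and -0.0027 for PDF1.2b. Without the lowest 30 percent, glutathione transferases were at 0.064 and serine carboxypeptidase-like genes at 0.0091; without the lowest 50 percent, glutathione transferases were at 0.071 and photosynthesis at -0.13. With the length trend removed, heat shock was at -0.00747, RALF-like peptides at -0.022, serine carboxypeptidase-like genes at 0.020, trichome birefringence-like genes at 0.024, chloroplast-encoded genes at -0.063 and ICL at 0.011. AT4G03410 was at -0.058 without probe sets among another chromosome. Leaving out single arrays gave ranges of -0.061 to 0.33 for AT4G21870, -0.20 to 0.078 for EEL, -0.050 to 0.41 for EXPA18, -0.27 to 0.14 for EXPA9, -0.11 to 0.019 for ICL, -0.29 to 0.43 for PDF1.2b, -0.00315 to 0.066 for RALF-like peptides, -0.035 to 0.12 for SWEET, -0.028 to 0.028 for beta-glucosidases, -0.012 to 0.029 for chloroplast-encoded genes, -0.019 to 0.060 for endosperm and seed coat, -0.12 to 0.083 for further small heat shock proteins, -0.053 to 0.084 for heat shock, -0.12 to 0.15 for photosynthesis and -0.034 to 0.011 for trichome birefringence-like genes. The WRKY43 level had no value in any setting, lists were not run with robust eBayes, and the pseudocount did not apply to log2 values.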

Other observations

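The tests of a segment around WRKY43 and of neighbouring genes were chosen only after the genes with the largest differences had been seen; the others were written down after the differences per gene, and before the values they measure, had been seen. Of the further cupins and oleosins, seed storage and oil body proteins, 8 of 9 read lower in wrky43-1, with a median log2 difference of -0.31 that narrowly missed the threshold (camera adjusted p = 0.05001, 0.752 with an estimated correlation, 0.146 in fry and 0.0252 with the length trend removed; range over its alternatives 0.00869 to 0.752), among them AT1G03890 (-1.29) and AT1G48990 (-0.36). AT1G03890 passed adjusted over the list alone (limma adjusted p = 0.0028). Of 25 cytochrome P450 genes 22 read lower (median -0.14, camera adjusted p = 0.125, fry adjusted p = 0.0375), among them CYP71B32 (-0.68). Of 7 core histone genes 5 read higher (median 0.19, camera adjusted p = 0.125, fry adjusted p = 0.0217), among them AT5G02570 (0.75). Of 17 RNA polymerase subunits 11 read higher (median 0.16, camera adjusted p = 0.161), among them NRPB6B (0.58), and of 25 further LEA and dehydrin genes 20 read higher (median 0.05, camera adjusted p = 0.185). Of 51 UDP-glycosyltransferases 34 read lower (median -0.06, camera adjusted p = 0.24), and UGT73B4 passed adjusted over the list alone (limma adjusted p = 0.0124).

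Other families were not called by camera and lay at medians from -0.07 for 14 glutathione transferases (adjusted p = 0.968) to 0.07 for 8 small heat shock proteins (0.968). Between them lay 22 expansins (-0.06, 0.431), 9 xyloglucan endotransglucosylases (-0.000416, 0.764), 22 beta-glucosidases (-0.02, 0.968), 14 SWEET transporters (0.05, 0.834), 15 RALF-like peptides (-0.0012, 0.766), 63 cysteine-rich peptides (-0.06, 0.766), 64 AGAMOUS-like genes (-0.04, 0.735), 32 serine carboxypeptidase-like genes (-0.05, 0.968), 23 trichome birefringence-like genes (-0.0021, 0.968), 8 photosystem and Calvin cycle genes (0.02, 0.766) and 63 chloroplast-encoded genes (-0.03, 0.968). The means of the beta-glucosidases, SWEET transporters, RALF-like peptides, photosystem and chloroplast-encoded genes were above 0 and turned below it with the arrays centred on the same median. Of the chloroplast-encoded genes psbM had the smallest p, with 11.78 in wrky43-1 against 10.68 in wild type (log2 difference 1.10, SE 0.14, limma adjusted p = 0.157). The 1604 distinct sets of probe sets with identical values had a median log2 difference of 0.13, with 60.5% higher in wrky43-1, and medians of -0.04 between the wild-type arrays and 0.03 between the wrky43-1 arrays.

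Genes of cytosolic ribosomal proteins were higher in wrky43-1 by a median of 0.34. Lists of other genes matched on level and length had a median of 0.10 (central 95% 0.04 to 0.17), and the highest of 10000 reached 0.22. The matched genes were drawn 1 by 1, so this range does not cover noise that the genes of a list share. With an estimated correlation the call of the list was lost (camera adjusted p = 0.752). The median of the list lay above the highest matched list, which was the bound set beforehand. This argues against gene length and signal level as the whole explanation, but leaves noise that the genes of the list share open. RNA integrity or labelling that differs from one extraction to the next may contribute: the larger median difference between arrays of a genotype was 0.219 times the one between genotypes, below the bound of 0.25 set beforehand, but its bootstrap interval of 0.123 to 0.295 crosses it. An effect of the genotype stays open too and was not tested, since any handling shared by both arrays of a genotype cannot be told apart from it.

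Long genes were lower in wrky43-1, with a slope of -0.151 on the log2 scale per unit of log10 gene length over 16411 genes (Spearman's rho -0.187 across genes, which are not independent replicates). The relation was not a steady one. Median differences lay between -0.022 and 0.029 in the bins up to 4000 bp, and below that range only in the bins of longer genes. Within 20 bins of mean level the slope was 1.28 times as large (bootstrap interval 1.24 to 1.33), which argues against signal level as the source of the slope. Whether the normalization itself depends on signal level was not tested by it. Differences did vary with level: genes of 1000 to 2000 bp had a median of 0.029, and those of them above the median level 0.129. The slope between arrays of a genotype reached 0.309 times the one between genotypes, between the bounds of 0.25 and 0.5 set beforehand, so an RNA integrity that differs between extractions stays open. Seed lot, harvest or RNA handling shared by both arrays of a genotype cannot be told apart from the genotype, because each genotype has only such arrays; an effect of the genotype itself was not tested.

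Genes that differ between the lines could reflect other differences in their genomes than the lesion in WRKY43. Within 1 Mb of WRKY43, 4.48% of 290 named genes had an unadjusted p under 0.01 (exact 95% interval 2.41% to 7.54%) against 2.52% of 16042 elsewhere, 1.78 times as many (Fisher's exact test, two-sided p = 0.0558). The upper bound of 7.54% lies within the error of the bound looked for, 3 times the share elsewhere (7.56%, or 6.84% from the lower limit of that share), so a linked segment is neither shown nor excluded. Of 15382 neighbouring pairs of named genes, 11 had both members at that p with the same sign, where 100000 permutations of gene order gave a median of 5 and a central 95% of 1 to 10 (permutation p = 0.0135). The pair of AT1G36920 and AT1G36922, seen before this test was chosen, is among the 11. The permutation p is therefore not free of what had been seen. Pairs that share a gene were counted apart: AT1G27750 pairs with STZ and with AT1G27752, and AT5G45470 with AT5G45469 and with AT5G45480. Permuted orders hold no likeness of neighbours from any source, so a surplus of pairs would not by itself point to the genome. As the highest permutation reached 16, local differences that move neighbours, such as AT1G36920 with AT1G36922, together remain open, as does an effect of WRKY43 itself, which was not tested.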
